A study of Homo sapiens with 20 samples.

How the data were processed

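RNA of whole skin was measured on 20 Affymetrix arrays, 1 per sample, with biotin-labelled total RNA per the labels' protocols. The deposited values are log2 expression values per probe set, made with GCRMA per the submitters' processing notes, whose version is not given in the sources used here. GCRMA adjusts the background by probe sequence, normalizes quantiles over arrays and summarises the probes of a set. That the scale is log2 was read from the values, which ran from 2.17 to 15.3, with array medians of 4.66 to 4.73 and upper quartiles of 7.61 to 7.70. All arrays shared a floor at the lowest value, which held 28.2% to 29.0% of the values of an array, so a change of a gene near the floor is compressed and its fold depends on the floor. Scanner files were not used here. The number of arrays limits the precision.

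Of 22277 probe sets, 62 were control probe sets. Genes were named through the platform annotation, which listed 20113 probe sets. It gave 1 gene for 19070, several genes for 1043, and 2108 probe sets were unnamed here. Of those with 1 gene, 19058 matched a reference entry by gene identifier, and 0 symbols had to be updated. Probe sets with several genes or none were left out of the gene tests, as were 37 of sex-linked genes and any control probe sets that the annotation listed. The remaining 19027 probe sets stood for 11935 genes. Each gene was represented by the probe set with the highest mean over the 20 arrays, and genes were tested where the log2 value was above 4 on at least 5 of the 20 arrays, which left 7862. Of the genes past the threshold, 2339 had several probe sets, and in 119 of these the probe sets passed the threshold in opposite directions.

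The labels gave each sample a patient and a group, 10 irradiated at 2 MED and 10 nonirradiated. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the values as deposited, with the patient as a block, two-sided, and Benjamini-Hochberg adjustment at 0.05. The block was part of the main design because the labels, not the values, pair the samples. As a check, the deviations of paired arrays from their group means correlated at 0.089 to 0.695 with a median of 0.431, against a median of -0.060 for arrays of different patients. A second count asked for a change of at least 2-fold. Patients are separate persons, so the p-values measure the spread of the change between persons.

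In all, 34 gene lists of pathways, cell types and control genes were fixed before the data were examined, as were the rule for named genes, the design and the other settings to try. Of 588 list entries, 489 were on the array, and 33 lists had at least 3 tested genes. Lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry beside it, each adjusted over the lists. Named genes were the 8 with the largest fold up and the 8 with the largest fold down among genes past the threshold that changed the same way in at least 9 of the 10 pairs, and of each list the 2 members past the threshold with the largest change and the 1 with the largest change against the majority of its called members. Relations between list changes used Pearson's r and Spearman's rho with exact permutation tests in scipy 1.17.1. They had been planned over all 10 pairs and were computed within 8, because 2 pairs formed a cluster of their own.

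The gene test was tested on simulated data with the 7862 genes of this comparison, of which 200 were changed. It recovered 54% of the genes changed by 0.5 and 88% of those changed by 1 on the log2 scale, and 8 of its 150 calls were unchanged genes. Of 200 random lists of 15 genes, 2 had a camera p under 0.05, while a list shifted by 0.5 had p = 3.28e-22. The simulated genes varied independently, so this does not show how camera behaves where the genes of a list vary together. In the measured lists the estimated correlation reached 0.758, for the cell cycle list.

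The other settings fixed in advance were quantile normalization, median centring, no filter, a filter on the mean, the mean of all probe sets of a gene, leaving out probe sets ending in _s_at or _x_at (classes that can match several transcripts), no block, the patient as a random block, an intensity trend with a robust prior, array weights, each pair left out in turn, a plain paired t-test and all probe sets tested separately. Chosen after seeing the data were leaving out the 2 pairs that stood apart and leaving out probe sets with ties, since 538 probe sets held 1 identical value above the floor on at least 10 arrays.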

Results

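Whole skin from 10 patients was profiled on 20 Affymetrix expression arrays, 10 of skin irradiated with narrow-band ultraviolet B at 2 MED (minimal erythema doses, multiples of the dose that just reddens a person's skin) and 10 of nonirradiated skin. Each patient gave 1 sample to each group, so every comparison was made within 10 pairs. The time between irradiation and sampling is not given in the sources used here. The comparison asks which transcripts differ between irradiated and nonirradiated skin, with the series' title pointing to innate immune responses. Changes are log2 irradiated minus nonirradiated values from limma with the patient as a block, ± standard error, n = 10 pairs, and adjusted p-values are two-sided after Benjamini-Hochberg adjustment. The number of arrays limits the precision of each value.

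Irradiated skin differed from nonirradiated skin in most genes tested. Of 7862 genes tested, 2496 rose and 2764 fell, and 604 rose and 605 fell at least 2-fold. The genes with the largest folds up included those of matrix-degrading enzymes, chemokines and an AP-1 component, and those with the largest folds down included WNT4, LGR5, OMD and CD207. The log2 difference between the 3' and 5' control probe sets of ACTB, a sign of RNA quality, was 5.12 ± 0.27 (SD, n = 10) in irradiated and 5.83 ± 0.29 (SD, n = 10) in nonirradiated skin. It was lower on the irradiated array in 10 of 10 pairs, by an exact two-sided permutation p of 0.00195, the smallest that 10 pairs allow. The same difference for GAPDH was 1.70 against 1.73, with an exact p of 0.826. Since the ACTB measure moved with irradiation, it stands beside every gene group described here.

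In 2 of the 10 pairs the changes differed from those of the other 8. Across the tested genes, the changes of any pair among those 8 correlated with each other at 0.780 to 0.863, those of the 2 with the 8 at 0.285 to 0.561, and those of the 2 with each other at 0.658. These correlations are across genes, which are not independent replicates. Where 2 values are given below for the 2 pairs that differed, the lower stands first, whichever pair it came from. Without these 2 pairs, a setting chosen after the data were examined, 2535 genes rose and 2976 fell, 730 and 785 of them at least 2-fold.

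The collagenase gene MMP1 showed the largest fold up among the genes chosen by the fixed rule, 149-fold (7.22 ± 0.48, adjusted p = 2.28e-06), from a mean log2 value of 2.51 in nonirradiated skin, close to the lowest value of the data. The stromelysin gene MMP3 rose 44.6-fold (5.48 ± 0.48). SERPINB4, a serine protease inhibitor of squamous epithelium, rose at least 92.6-fold (6.53 ± 0.46), with 7 of the 10 nonirradiated arrays at the floor, on a probe set of a class that can match related transcripts. The chemokine genes CXCL1 (5.92 ± 0.53), CCL20 (5.71 ± 0.74) and CXCL2 (5.17 ± 0.57) rose, as did FOSL1 (5.78 ± 0.40), a component of the AP-1 transcription factor, and PI3 (5.16 ± 0.37), which codes for the elastase inhibitor elafin. All 8 genes were higher in 10 of 10 pairs. CXCL2 was read on an _x_at probe set, as were SPRR2B, MT2A and CD163 below, and other named genes on _s_at or _x_at sets. Such sets can match several transcripts, so these changes need not be those of the named gene alone. Because values near the array floor are compressed, the changes of genes with a mean near it in either group depend on the floor. With the mean of all probe sets of a gene, the changes of 8 genes named in this text were over 1.5 times smaller with their calls kept, those of LAMB4 (-1.95), LGR5 (-1.76), DST (-0.59), POSTN (-1.56), DBP (-1.25), FPR1 (2.32), SDC1 (-0.60) and POLR2A (0.23).

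Among the genes with the largest folds down, CHP2, coding for a calcium-binding cofactor of sodium-proton exchangers, fell 22.8-fold (-4.51 ± 0.59, adjusted p = 5.52e-05) and the Wnt ligand gene WNT4 fell 17.7-fold (-4.15 ± 0.64). LGR5, which codes for a receptor of R-spondins and marks stem cells in several epithelia, fell by 3.52 ± 0.33. LRRC17 (-3.72 ± 0.23), the laminin chain gene LAMB4 (-3.52 ± 0.31), the proteoglycan gene OMD (-3.41 ± 0.21) and the amino acid transporter gene SLC16A10 (-3.32 ± 0.29) also fell, as did CD207 (-3.29 ± 0.56), which codes for langerin. Of these 8 genes, 7 were lower in 10 of 10 pairs and WNT4 in 9. CHP2 changed by -0.60 and -0.46, and WNT4 by -0.43 and 0.58, in the 2 pairs that stood apart, against at most -4.85 and -4.24 in the other 8.

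**Figure D1:**
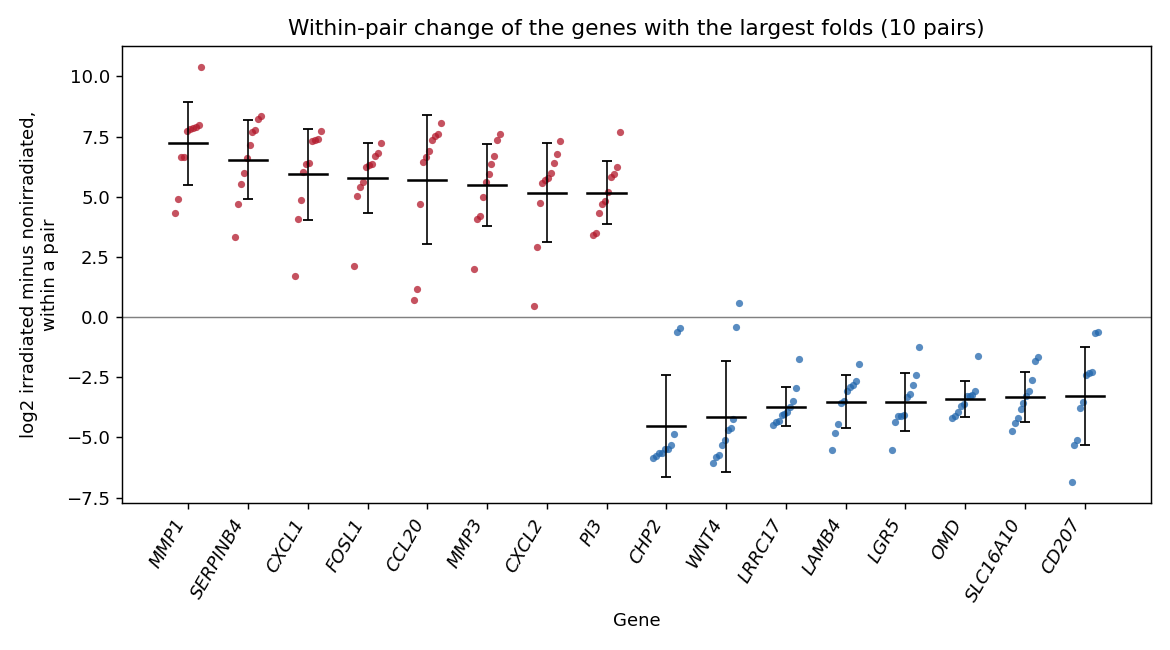
Within-pair log2 changes, irradiated minus nonirradiated, of the 8 genes with the largest folds up (red) and the 8 with the largest folds down (blue). Each point is 1 of the 10 pairs, black lines are means and error bars 1 SD over pairs. All points lie above 0 for the 8 higher genes, and WNT4 is the only lower gene with a pair above 0.

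Of the 33 gene lists with at least 3 tested genes, 16 shifted against all other genes by camera with a preset correlation of 0.01, 10 up and 6 down. With a correlation estimated from the data, 0 of the 33 did. By fry, which tests a list by itself, 22 did, both control lists among them. At an unadjusted p under 0.05, limma counted 5471 single genes. With genes kept by a mean above 5, where 6973 were tested, 8 of the 16 calls ended, those of antimicrobial proteins, clock, melanocytes, neutrophils, Langerhans cells, endothelium, adipocytes and sweat glands (adjusted p of 0.0582 to 0.281). The same 8 calls and that of the NRF2 list ended without probe sets of the classes that can match several transcripts (adjusted p of 0.0522 to 0.204), and those of melanocytes, Langerhans cells and endothelium with the mean of all probe sets of a gene (adjusted p of 0.0556 to 0.0567). The lists described below were fixed before the data were examined, and the counts of members are over all 7862 genes tested unless said otherwise.

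Among the lists with at least 3 tested genes, innate cytokines and chemokines had the highest median change. In this list 16 of 17 tested genes rose and 0 fell, 16 and 0 adjusted over the list alone, with a median change of 2.48 (camera adjusted p = 4.69e-05, adjusted p = 0.534 with an estimated correlation). Of its members, 25 were on the array. Genes dim in nonirradiated skin could pass the filter through their irradiated arrays alone, so the share that rose and the median may be too high. With no filter on dim genes its call held (camera adjusted p = 3.62e-05, but 0.408 with an estimated correlation). IL6 rose by 5.07 ± 0.77 and CXCL8, the neutrophil chemokine gene, by 4.61 ± 0.73, both named after their values were seen. The mean change of the list was 2.76 to 4.54 in 8 pairs, and 0.072 and 0.754 in the 2 pairs that stood apart, where IL6 and CXCL8 changed by at most 0.017. Changes so close to 0 may mean that both arrays of these pairs lay at the floor, where a change is not resolved. Of the epidermal antimicrobial proteins and alarmins, 7 of 10 rose and 1 fell, 7 and 1 adjusted over the list alone, with a median of 2.43 (camera adjusted p = 0.0207, adjusted p = 0.534 with an estimated correlation). S100A9, a subunit of calprotectin, rose 28.7-fold (4.84 ± 0.39), and the constitutive defensin gene DEFB1 fell by 0.46 ± 0.13. In the 2 pairs that stood apart the mean change of this list was 0.945 and 1.44, against 1.63 to 4.04 in the other 8, and S100A9 changed by 3.16 and 3.48.

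Genes of the neutrophil and myeloid lists rose. Of the neutrophil genes, 7 of 9 rose and 0 fell, 7 and 0 adjusted over the list alone, with a median of 1.53 (camera adjusted p = 0.0227, adjusted p = 0.534 with an estimated correlation). The formyl peptide receptor gene FPR1 rose 24.9-fold (4.64 ± 0.71), and S100A12 8.48-fold (3.08 ± 0.52). At the floor lay 6 and all 10 of the nonirradiated arrays and 1 and 2 of the irradiated arrays, so both folds depend on the floor. The median of the neutrophil list was 0.89 with a mean above 5 as the filter and 0.76 with no filter on dim genes. Of the genes of monocytes, macrophages and inflammatory myeloid cells, 14 of 18 rose and 0 fell, 15 and 1 adjusted over the list alone, with a median of 0.93 (camera adjusted p = 0.00172, adjusted p = 0.534 with an estimated correlation). The scavenger receptor gene CD163 rose by 2.26 ± 0.37 and the Fc receptor gene FCGR2A by 1.94 ± 0.35. In the 2 pairs that stood apart, the mean change was 0.225 and 0.491 for the neutrophil list and -0.165 and 0.439 for the myeloid list, against 1.21 to 2.86 and 0.671 to 1.71 in the other 8. The endothelium and adhesion list had 9 of 13 genes higher and 3 lower, 10 and 3 adjusted over the list alone, with a median of 0.65 (camera adjusted p = 0.0373, adjusted p = 0.591 with an estimated correlation). Its leading members SELE (3.94 ± 0.50) and ICAM1 (2.53 ± 0.34) code for adhesion molecules that leukocytes bind on activated endothelium, while the tight junction gene CLDN5 fell by 0.66 ± 0.14. Both pairs that stood apart had a mean change of 0.1 in this list. The call of the endothelium list ended without 1 of the pairs (adjusted p = 0.0644) and without the patient block (adjusted p = 0.0731). It also ended with the patient as a random block (adjusted p = 0.0642).

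Marker genes of Langerhans cells and melanocytes were lower in irradiated skin. Of the Langerhans cell genes, 5 of 7 fell and 1 rose, 6 and 1 adjusted over the list alone, with a median of -1.25 (camera adjusted p = 0.0373, adjusted p = 0.534 with an estimated correlation). CD1A fell by 2.94 ± 0.43 beside CD207, and the exception was CLEC10A (0.70 ± 0.26, adjusted p = 0.0303), which other dendritic cells and macrophages also express. The mean change of the Langerhans list was -0.909 and -0.687 in the 2 pairs that stood apart, where CD207 changed by -0.683 and -0.631, against -2.81 to -0.753 for the list and -6.86 to -2.27 for CD207 in the other 8. The call of CLEC10A ended without any 1 of 4 pairs (adjusted p of 0.0647 to 0.0698) and with no filter on dim genes (adjusted p = 0.0695). Of the melanocyte and pigment synthesis genes, 8 of 9 fell and 0 rose, 8 and 0 adjusted over the list alone, with a median of -1.15 (camera adjusted p = 0.0373, adjusted p = 0.536 with an estimated correlation). OCA2 fell by at least 2.08 ± 0.34, with 8 of the 10 irradiated arrays at the floor, and TYR, coding for tyrosinase, by 1.62 ± 0.42. The mean change of the melanocyte list was -1.76 to -1.04 in 8 pairs, and -0.066 and 0.643 in the 2 pairs that stood apart. Its call ended without 1 of the pairs (adjusted p = 0.0584), without the patient block (adjusted p = 0.0717) and with the patient as a random block (adjusted p = 0.0625).

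Genes of several stress responses rose. Of the AP-1 and immediate early genes, 13 of 16 rose and 0 fell, 13 and 0 adjusted over the list alone, with a median of 1.13 (camera adjusted p = 5.36e-04, adjusted p = 0.534 with an estimated correlation), and FOSB rose 18.9-fold (4.24 ± 0.42). The target genes of the tumour suppressor p53 had 11 of 17 members higher and 1 lower, 12 and 1 adjusted over the list alone, with a median of 0.82 (camera adjusted p = 0.00172, adjusted p = 0.534 with an estimated correlation). TIGAR, a regulator of glycolysis, rose 8.80-fold (3.14 ± 0.24) and the cell cycle inhibitor gene CDKN1A 4.48-fold (2.16 ± 0.24), while DDB2, coding for a sensor of ultraviolet damage, fell by 1.13 ± 0.19. Of the NRF2 and oxidative stress genes, 10 of 13 rose and 1 fell, 10 and 1 adjusted over the list alone, with a median of 0.94 (camera adjusted p = 0.00647, adjusted p = 0.534 with an estimated correlation). AKR1B10 rose by 3.24 ± 0.29 and the metallothionein gene MT2A by 1.66 ± 0.18, and GCLC, which codes for an enzyme of glutathione synthesis, fell by 0.84 ± 0.13. The median of the NRF2 list was 0.57 without _s_at and _x_at probe sets and 0.56 with the mean of all probe sets of a gene. Of the type I interferon response genes, 11 of 17 rose and 0 fell, 11 and 0 adjusted over the list alone, with a median of 0.75 (camera adjusted p = 0.00172, adjusted p = 0.534 with an estimated correlation), among them MX2 (2.15 ± 0.28) and ISG15 (1.87 ± 0.16). The mean changes of the p53, NRF2 and type I interferon lists were above 0 in 10 of 10 pairs. The AP-1 list changed by 0.1 and 1.30 in the 2 pairs that stood apart and by 1.19 to 2.08 in the other 8, and the type I interferon list by 0.282 and 0.326 against 0.340 to 1.73.

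Genes past the threshold mostly rose in the list of matrix metalloproteinases and inhibitors and mostly fell in the dermal matrix list. Of the matrix metalloproteinases and inhibitors, 7 of 13 rose and 1 fell, 7 and 1 adjusted over the list alone, with a median of 1.29 (camera adjusted p = 0.0231, adjusted p = 0.534 with an estimated correlation), and the inhibitor gene TIMP3 fell by 1.19 ± 0.12. The mean change of this list was 0.558 and 0.922 in the 2 pairs that stood apart, and 1.71 to 2.44 in the other 8. Its call held with smaller medians with no filter on dim genes (0.40), with the mean of all probe sets of a gene (0.61) and without _s_at and _x_at probe sets (0.36). Of the collagens and dermal matrix genes, 15 of 17 fell and 1 rose, 15 and 1 adjusted over the list alone, with a median of -0.74 (camera adjusted p = 6.49e-04, adjusted p = 0.534 with an estimated correlation). POSTN, coding for periostin, fell 5.07-fold (-2.34 ± 0.15), COL3A1 fell by 1.26 ± 0.20, and COL6A3 rose by 0.38 ± 0.12. The mean of the dermal list was below 0 in all 10 pairs, -0.759 and -0.721 in the 2 that stood apart. Of the adipocyte genes 7 of 8 fell and 0 rose, 7 and 0 adjusted over the list alone, with a median of -1.05 (camera adjusted p = 0.0488, adjusted p = 0.534 with an estimated correlation), and of the sweat gland genes 6 of 8 fell and 0 rose, 6 and 0 adjusted over the list alone, with a median of -1.38 (camera adjusted p = 0.0488, adjusted p = 0.603 with an estimated correlation). ADIPOQ, coding for adiponectin, fell by 1.84 ± 0.41, FABP4 fell by 1.29 ± 0.29, and the secretory genes SCGB1D2 (-1.93 ± 0.42) and PIP (-1.72 ± 0.36) fell too. In the 2 pairs that stood apart the sweat gland list had a mean change of -0.669 and 0.622, against a median of -1.62 and a range of -2.57 to 0.085 in the other 8, and that of the adipocyte list -1.21 and -0.940 against -2.20 to 0.138. Without the patient block the calls of both lists ended (adjusted p of 0.389 for adipocytes and 0.175 for sweat glands), as did those of ADIPOQ (0.181), FABP4 (0.196) and PIP (0.104). With the patient as a random block, the calls of both lists (adjusted p of 0.319 and 0.143), ADIPOQ (0.0824) and FABP4 (0.0919) also ended. That fit sets 1 correlation within patients, 0.261, for all genes, and its list test used the finished gene statistics. It keeps only part of the pairing of genes that differ much between patients. ADIPOQ was lower in 10 of 10 pairs and FABP4 in 8. The change of ADIPOQ had an SD of 1.48 over pairs, against 3.06 over irradiated and 2.48 over nonirradiated arrays. Both list calls also ended under quantile normalization (adjusted p of 0.0508 and 0.0535), median centring (0.0504 for both) and array weights (0.0668 and 0.0557), the adipocyte call without any 1 of 5 pairs (0.0516 to 0.0706) and without the 2 pairs that stood apart (0.102), and the sweat gland call without any 1 of 7 pairs (0.0516 to 0.0706).

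Genes of the core circadian clock list were lower in irradiated skin. Of the core circadian clock genes, 7 of 12 fell and 0 rose, 7 and 0 adjusted over the list alone, with a median of -0.63 (camera adjusted p = 0.0373, adjusted p = 0.534 with an estimated correlation). The transcription factor genes DBP (-2.52 ± 0.40) and HLF (-2.09 ± 0.25) fell. The mean of the list was below 0 in all 10 pairs, -0.273 and -0.271 in the 2 that stood apart and -1.28 to -0.719 in the other 8. Its call ended without the patient block (adjusted p = 0.0661) and with the patient as a random block (adjusted p = 0.0625). The median of the list shrank to -0.32 with a mean above 5 as the filter and to -0.13 without _s_at and _x_at probe sets.

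Keratinocyte genes went both ways. KRT16, a keratin of stressed and wounded epidermis and the only member of its list measured by probe sets of a single gene, rose by 2.58 ± 0.48, and its list was not tested as a set. Of the cornified envelope and terminal differentiation genes, 6 rose and 11 fell of 20, 6 and 11 adjusted over the list alone, with a median of -0.48 (camera adjusted p = 0.223). SPRR2B, coding for a cornified envelope protein of stressed epidermis, rose by 2.24 ± 0.27, and LCE2B, coding for one of late differentiation, fell by 2.19 ± 0.25. This list had a mean change of 0.162 and 0.701 in the 2 pairs that stood apart, and one below 0 in 7 of the other 8 (median -0.382). Of the basal keratinocyte and basement membrane genes, 4 of 8 fell and 0 rose, 4 and 0 adjusted over the list alone, with a median of -0.58 (camera adjusted p = 0.0616), among them KRT15 (-2.34 ± 0.34) and DST (-1.60 ± 0.21). In the 2 pairs that stood apart the basal list had a mean change of -0.108 and 0.176, against -1.86 to -0.634 in the other 8. The list passed the threshold without 1 of the pairs (adjusted p = 0.0381), without the 2 pairs that stood apart (adjusted p = 0.0314, median -0.88), with no filter on dim genes (adjusted p = 0.0319) and with array weights (adjusted p = 0.0475). With an estimated correlation none of these 4 calls held (adjusted p of 0.472 to 0.577). Its median was -0.37 with the mean of all probe sets of a gene and -1.0 without _s_at and _x_at probe sets. Of the cell cycle and proliferation genes, 8 fell and 3 rose of 20, 8 and 3 adjusted over the list alone, with a median of -0.41 (camera adjusted p = 0.349). TOP2A fell by 1.78 ± 0.43 and NUSAP1 by 1.72 ± 0.31, both genes of mitosis, while PCNA, the sliding clamp of DNA synthesis and repair, rose by 0.57 ± 0.11. The mean change of this list was -1.52 to -0.311 in 8 pairs, and 0.756 and 0.769 in the 2 pairs that stood apart. Without those 2 pairs, 14 fell and 3 rose, and the list passed the threshold (adjusted p = 0.046, but adjusted p = 0.574 with an estimated correlation), as it did with no filter on dim genes (adjusted p = 0.047, but 0.709).

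**Figure D2:**
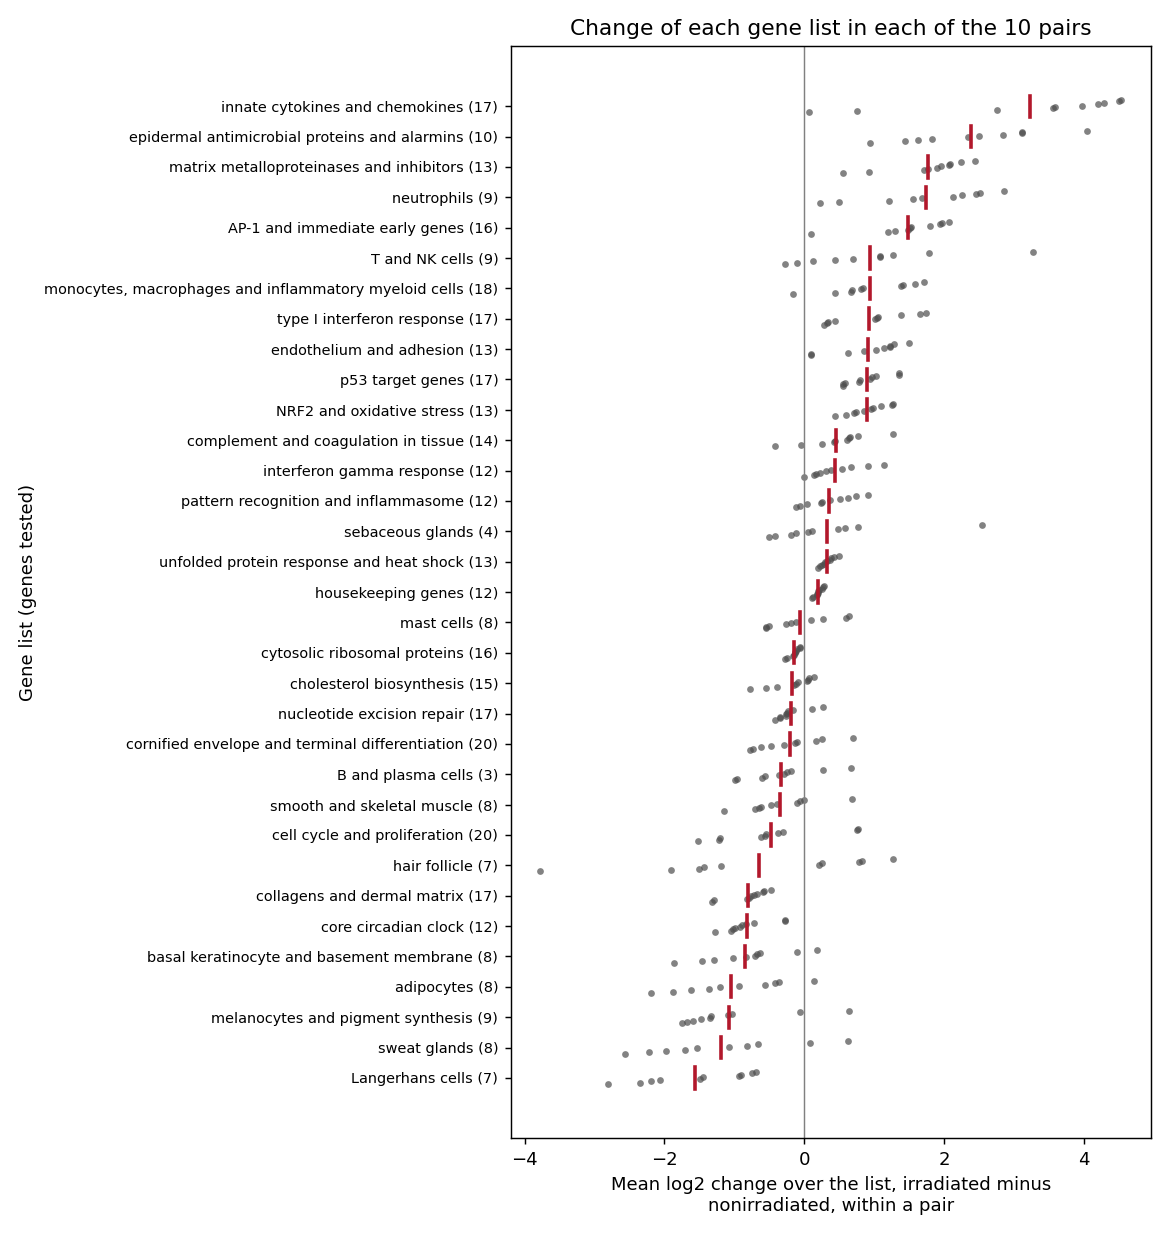
Mean log2 change, irradiated minus nonirradiated, over the tested members of each gene list, with the number of genes in brackets. Each grey point is 1 of the 10 pairs and red lines are means over pairs. In the list of innate cytokines and chemokines, 2 pairs lie at 0.072 and 0.754 and the other 8 between 2.76 and 4.54.

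The remaining lists did not pass the camera threshold as sets. Of the unfolded protein response and heat shock genes 7 of 13 rose and 1 fell, 7 and 1 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.0616). The chaperone gene HSPH1 rose by 1.57 ± 0.13 and HSPB1 fell by 1.10 ± 0.23. With no filter on dim genes this list passed the threshold (adjusted p = 0.0321, but 0.408 with an estimated correlation, median 0.18). Of the nucleotide excision repair genes, 7 fell and 1 rose of 17, 7 and 1 adjusted over the list alone (camera adjusted p = 0.405), and its median of 0.0024 had the opposite sign to its mean of -0.190 and to both set tests, and turned to -0.0099 under quantile normalization. Nucleotide excision repair genes had a mean change of -0.419 to -0.167 in 8 pairs, and of 0.116 and 0.265 in the 2 pairs that stood apart. POLE fell by 0.76 ± 0.16, and ERCC1 rose by 0.37 ± 0.10, a change of the same size without the patient block but with no call there (adjusted p = 0.0581). The interferon gamma response had 6 of 12 genes higher and 1 lower, 6 and 1 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.140). IDO1 rose by 1.81 ± 0.32, a size that depends on the floor, where all 10 nonirradiated and 2 irradiated arrays lay. WARS1 rose by 1.62 ± 0.09, and GBP2 fell by 0.84 ± 0.08. In the complement and coagulation list 6 of 14 rose and 1 fell, 6 and 1 adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.175, and 0.0492 without the 2 pairs that stood apart, where adjusted p = 0.472 with an estimated correlation). The anaphylatoxin receptor genes C5AR1 (2.46 ± 0.41) and C3AR1 (2.17 ± 0.40) rose and F3, coding for tissue factor, fell by 1.36 ± 0.19. In the 2 pairs that stood apart the complement list had a mean change of -0.418 and -0.05, against 0.255 to 1.27 in the other 8, and that of the interferon gamma list -0.01 and 0.219 against 0.135 to 1.14. Pattern recognition and inflammasome genes included 7 of 12 higher and 3 lower, 7 and 3 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.130), with TLR2 (1.53 ± 0.33) and NOD1 (1.28 ± 0.17) higher and NLRP1 lower (-1.24 ± 0.11). Cholesterol biosynthesis had 3 of 15 genes lower and 0 higher, 2 and 0 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.258). LSS fell by 1.03 ± 0.14, and DHCR7 by 0.32 ± 0.12. The call of DHCR7 ended without any 1 of 6 pairs (adjusted p of 0.063 to 0.0883) and with no filter on dim genes (0.0674). It also ended without the patient block (0.518) and with the patient as a random block (0.386).

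Among other cell types, 3 of 9 T and NK cell genes rose and 0 fell, 2 and 0 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.115). Among them were the cytotoxic granule gene GZMB (3.32 ± 0.51) and the chemokine receptor gene CCR7 (1.89 ± 0.30). For GZMB, 7 of the 10 nonirradiated arrays and 1 irradiated array lay at the floor, so its change depends on the floor. With no filter on dim genes the list passed the threshold (adjusted p = 0.0335, but 0.574 with an estimated correlation, median 0.32). Mast cell genes had 2 higher and 2 lower of 8, 2 and 2 adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.708). The IgE receptor gene FCER1A, also a member of the Langerhans cell list, fell by 1.18 ± 0.16. The chymase gene CMA1 rose by 1.10 ± 0.25, a change of the same size without the patient block but with no call there (adjusted p = 0.0677). Of the B and plasma cell genes 1 of 3 fell and 0 rose, 1 and 0 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.751), and this gene, SDC1 (-1.04 ± 0.19), is also expressed by keratinocytes. The median turned to 0.0046 for the B and plasma cell list without the 2 pairs that stood apart, and to 0.02 for the mast cell list without _s_at and _x_at probe sets. The sebaceous gland list had 0 of 4 genes past the threshold, adjusted over the list alone as well, with a median of 0.39 (camera adjusted p = 0.599). Of the hair follicle genes 1 of 7 fell and 0 rose, 1 and 0 adjusted over the list alone, with a median of -0.62 (camera adjusted p = 0.405), this gene being KRT31 (-2.55 ± 0.63). Of the smooth and skeletal muscle genes 5 of 8 fell and 0 rose, 5 and 0 adjusted over the list alone, with a median of -0.42 (camera adjusted p = 0.195), among them MYH11 (-0.72 ± 0.17) and CNN1 (-0.71 ± 0.19), whose calls ended without the patient block (adjusted p of 0.0667 and 0.0848). The antimicrobial gene DEFB1 lost its call in the same way (0.110).

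The control lists had small median changes. By fry, however, both passed the threshold, the ribosomal list at an adjusted p of 3.84e-04 and the housekeeping list at 5.03e-06. Of the cytosolic ribosomal protein genes 7 of 16 fell and 0 rose, 6 and 0 adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.0616, and 0.0393 without the patient block, where adjusted p = 0.570 with an estimated correlation). With the patient as a random block this list passed the threshold too (adjusted p = 0.0381). RPL3 fell by 0.49 ± 0.07 and RPL11 by 0.33 ± 0.06, and the list passed the threshold with no filter on dim genes (adjusted p = 7.22e-04, but 0.408 with an estimated correlation). Of the housekeeping genes 6 of 12 rose and 2 fell, 6 and 2 adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.145), including TFRC (0.78 ± 0.17) and POLR2A (0.70 ± 0.11) higher and GUSB lower (-0.34 ± 0.07), and this list passed the threshold with no filter on dim genes (adjusted p = 0.0424, but 0.408 with an estimated correlation). ACTB, whose control probe sets gave the RNA quality measure, rose by 0.45 ± 0.06.

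Because 2 pairs formed a cluster of their own, the 3 relations between list changes that had been fixed in advance were computed within the other 8 pairs, with exact two-sided permutation tests and adjustment over the 3. The change of KRT16 and that of the cornified envelope list had a Pearson r of 0.836 (exact p = 0.00883, adjusted p = 0.0265) and a Spearman rho of 0.714 (exact p = 0.0576, adjusted p = 0.0864). Without the 2 pairs farthest from the median of KRT16, r was 0.566 (exact p = 0.249). Fewer pairs over a narrower range can lower r by themselves, so whether the relation rests on those pairs stays open. With the median instead of the mean change of the list, r was 0.229 (exact p = 0.546). The changes of innate cytokines and of neutrophil genes had an r of 0.635 (exact p = 0.0881, adjusted p = 0.132) and a rho of 0.786 (exact p = 0.0279, adjusted p = 0.0838), with r at 0.470 without the 2 pairs farthest from the median. For p53 target genes and innate cytokines, r was -0.416 (exact p = 0.301, adjusted p = 0.301) and rho -0.333 (exact p = 0.428, adjusted p = 0.428), with r at -0.423 without the 2 farthest pairs. With list medians instead of means, this r was -0.614 (exact p = 0.120, adjusted p = 0.260) and rho -0.857, which passed the threshold (exact p = 0.0107, adjusted p = 0.0321). With list means, the relations of cytokines with neutrophil genes and of p53 targets with cytokines did not pass the threshold after adjustment. For cytokines with neutrophil genes, list medians gave an r of 0.543 (adjusted p = 0.260) and a rho of 0.452 (adjusted p = 0.401).

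**Figure D3:**
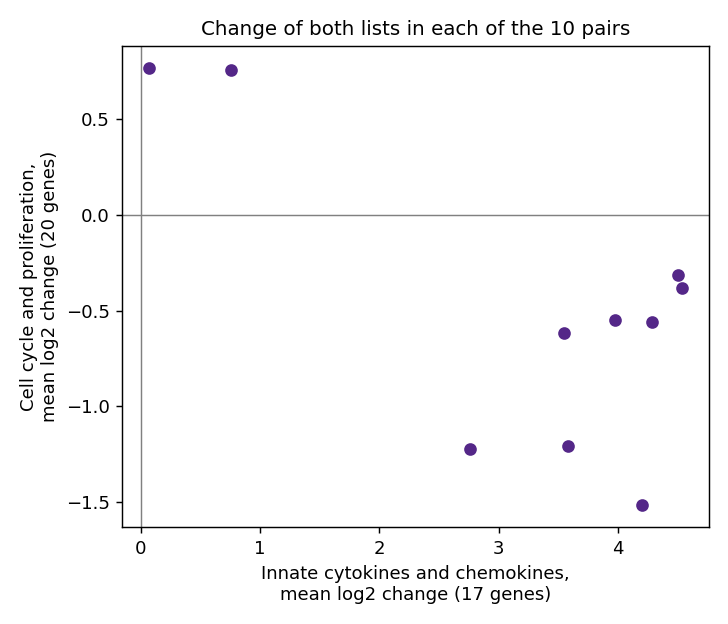
Mean log2 change, irradiated minus nonirradiated, of the innate cytokine and chemokine list (17 genes, horizontal) against that of the cell cycle and proliferation list (20 genes, vertical). Each point is 1 of the 10 pairs. The 2 pairs with positive cell cycle changes, 0.756 and 0.769, are also the 2 with the lowest cytokine changes, 0.072 and 0.754, the lower value of each list first.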

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

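The tests of a uniformly weaker response, of a smaller share of dermis and of the time of day were chosen only after the results they bear on were seen, as were the counts over other groupings; the tests of RNA quality, adipose tissue and sweat glands were set before their values were computed.

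Within groups of 10 arrays, 18 of 234 sets of values had a highest or lowest array with a gap to the next that took an unusually large share of the whole range, where chance gives about 1 in 20. In irradiated skin, the lowest array stood off for CXCL1 (0.588 of the range, 4.05 against 7.76 for the next), FOSL1 (0.583, 4.31 against 7.38) and TFRC (0.468), and the highest for LGR5 (0.708, 6.53 against 3.45), OMD (0.553), GCLC (0.483) and the list of B and plasma cells (0.714). In nonirradiated skin, the highest array stood off for MMP3 (0.928, 4.04 against 2.59), FOSB (0.737, 7.0 against 3.79), FPR1 (0.676), GZMB (0.658), the innate cytokine list (0.564), ERCC1 (0.527) and CCL20 (0.492), and the lowest for HSPB1 (0.687), CNN1 (0.5) and the cornified envelope list (0.486). For S100A12 in nonirradiated skin the share was 1.0, with all 10 arrays at the floor, so the gap was 2.18 against 2.17. Outside the gene tests, 427 of 628 tested probe sets assigned to several genes passed the threshold, 192 higher and 235 lower, and so did 468 of 757 unnamed probe sets, 180 higher and 288 lower.

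In the 2 pairs whose changes stood apart, MMP1 changed by 4.32 and 4.91 (6.63 to 10.4 in the other 8), PI3 by 4.31 and 4.68 (3.41 to 7.69), S100A9 by 3.16 and 3.48 (3.67 to 7.16), FPR1 by 0.015 and 0.241 (3.79 to 7.06) and C5AR1 by -0.190 and 0.118 (1.47 to 3.75). The sign of the cell cycle list was not that of a uniformly weaker response. The mean of this list rose by 0.756 (SE over genes 0.133) and 0.769 (SE 0.082) in these pairs and was below 0 in all other 8. The list was picked after its sign was seen, in pairs picked for changes unlike the others. It therefore describes these pairs and is no independent test of that explanation. The genes of this list vary together within a pair, so these standard errors understate the error. Of the named members of the cell cycle list, TOP2A changed by -0.558 and 0.196 and NUSAP1 by -0.143 and 0.165 in these pairs, on both sides of 0. PCNA changed by 0.690 and 1.09 in these pairs, but it also rose in the other 8 (0.179 to 1.19). Lower RNA quality stays open. Of the 4 arrays of the 2 pairs, 1 lay above the highest log2 3' to 5' difference of the other 16, in ACTB (6.27 against 6.24). The counts set in advance were 3 for lower quality and 0 against it. In ACTB the difference was lower on the irradiated array of every pair. Irradiated arrays could thus hardly pass a limit taken over both groups, and the count cannot decide. In GAPDH, where the groups did not differ, 0 of the 4 lay above. A different interval between irradiation and sampling may also account for the changes of the 2 pairs, but the labels give no time, so this was not tested.

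Most genes of the dermal matrix, adipocyte and sweat gland lists were lower in irradiated skin, and a biopsy holding less of the deeper skin is a candidate explanation. Among other lists of the deeper skin, 5 of 8 muscle genes and 1 of 7 hair follicle genes were lower and 0 higher in either list. Of the sebaceous gland genes 0 of 4 passed the threshold. The endothelium and adhesion list had 9 of 13 genes higher and 3 lower. Its rise was led by SELE and ICAM1, genes of activated endothelium, but other members rose too. So this list as a whole did not fall, as less of the deeper skin would have it. Irradiation may itself have raised its genes, so the list cannot decide on the depth of a biopsy. For the dermal matrix, 10 of 17 members lay more than 2 standard errors from the list's median of -0.741, so the members did not all fall alike. This was the outcome set against a smaller share of dermis. Members that other cells also express would fall less with a smaller share of dermis, so the test cannot decide for or against it. For sweat glands, the changes of the 8 members correlated over pairs at a mean of 0.673. In 1000 random lists the median was 0.002 and the 95th percentile 0.188. This met the value set in advance for fewer sweat glands in some irradiated biopsies (PIP, a member, went from a mean log2 value of 12.3 to 10.6). Genes regulated together also vary together, and the correlation estimated by camera was 0.758 for the cell cycle list and 0.634 for innate cytokines. The value for sweat glands therefore cannot tell fewer glands from a lower expression. For adipocytes, among which FABP4 went from 11.3 to 10.05, the mean correlation was 0.370, between the values set in advance for and against, so less adipose tissue and a lower expression cannot be told apart with these pairs. Neither of these 2 lists shares a member with another fixed list, and an effect of irradiation on these cells stays open.

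Of the core circadian clock list, 7 of 12 genes fell in irradiated skin, DBP and HLF among them, and a different time of day of sampling at the 2 sites may produce such a shift. Its expected sign in BMAL1 and NPAS2, which cycle opposite to DBP, would be a rise, and their mean change was -0.434 (SE over pairs 0.076). Both genes belong to this list, of which 0 rose, and the test was chosen after that was seen. The absence of a rise was thus known beforehand, and the value is no independent test. It shows only that these 2 genes did not move as a time of day alone would have it. Time of day is not excluded, and irradiation itself, the factor of the design, stays a hypothesis.

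For the number of genes past the threshold, the labels were flipped within pairs in 99 further groupings. The real grouping gave 5260 genes and the highest other 3733, so that only the real one of 100 was as large, which argues against chance. For genes changed at least 2-fold it gave 1209 against a highest other of 766, again with 1 of 100 as large. That is the smallest share that 100 groupings allow, so chance is made unlikely but is not excluded. For both counts the highest other grouping flipped 1 pair, so it differed least from the real grouping. For the 16 gene lists, 14 of 100 groupings gave as many, with a highest other of 21 and a median of 9 over the others, so chance cannot be excluded for the number of lists.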

How the results depend on the processing

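Leaving out the 2 pairs that stood apart, leaving out tied probe sets and computing the relations within 8 pairs were chosen only after the data were examined. The numbers of genes stayed within 1.5 times of the reported ones under every alternative run except without _s_at and _x_at probe sets, where fewer genes were tested (4788) and 3163 passed the threshold, 771 of them at least 2-fold, with 7 lists. The others gave 4686 to 5647 genes, and 7319 of 11132 probe sets tested separately. Without the block for the pairing the counts were 4764 genes, 1177 at least 2-fold and 12 lists. The calls of 5 lists and 9 named genes ended, 1 list gained a call, and no other call of a list or named gene changed. With the patient as a random block, which sets 1 correlation within patients for all genes, the counts were 5240 genes, 1198 at least 2-fold and 12 lists. There the calls of 5 lists and 3 named genes ended and 1 list gained a call. With each pair left out in turn, the counts ranged from 4909 to 5397 genes, 1093 to 1365 at least 2-fold and 14 to 15 lists. With a mean above 5 as the filter, 8 lists passed, and with an estimated correlation 0; the cause was not tested for these. Fry called 22 lists, no filter on dim genes 22 and the fit without the 2 pairs that stood apart 18. The relation of KRT16 with the cornified envelope list fell to an r of 0.2285 with list medians, the cause of which was not tested, and to 0.5661 with fewer pairs. Over lists and alternatives, 704 results kept their side of the threshold, 67 lost and 19 gained it, and of the named genes 1788 kept it and 24 lost it, with no reversal among them. Of the genes called in the main setting and tested in both, the mean of all probe sets turned 29 to a call in the opposite direction and leaving out _s_at and _x_at sets 19. Scaling moved the median of all genes by less than 0.1. Signal over background limits genes near the floor most.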

Other observations

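All of the gene families here were chosen after the values were seen, 26 in number, 25 with at least 3 tested genes, of which 10 passed camera at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.306). All camera p-values are adjusted over the 25. Of 33 ribosome biogenesis factors, 29 rose and 3 fell, with a median log2 change of 0.93 (camera adjusted p = 3.43e-09, adjusted p = 0.306 with an estimated correlation), led by members that reached 1.80. Among 33 proteasome subunits, 27 rose and 0 fell (median 0.50, camera adjusted p = 4.40e-07, adjusted p = 0.306 with an estimated correlation), and among 16 cytosolic aminoacyl-tRNA synthetases 13 rose and 1 fell (median 0.41, camera adjusted p = 7.67e-04, adjusted p = 0.306 with an estimated correlation). The mean change of each of these 3 families was above 0 in 10 of 10 pairs, the 2 that stood apart included. The cytosolic ribosomal protein genes, in contrast, had 7 of 16 lower and 0 higher.

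Several families of the matrix and of signalling were lower. Of 9 small leucine-rich proteoglycans, which organise collagen fibrils, 8 fell and 1 rose (median -1.11, camera adjusted p = 0.00832, adjusted p = 0.306 with an estimated correlation), with OMD (-3.41) the most changed and FMOD (0.38) the exception. Of 21 genes for Wnt ligands, receptors and antagonists, 14 fell and 2 rose (median -0.70, camera adjusted p = 0.00769, adjusted p = 0.306 with an estimated correlation). Of the corticosteroid genes all 5 tested fell, the receptors NR3C1 (-1.14) and NR3C2 (-1.79), the enzymes HSD11B1 (-0.42) and HSD11B2 (-0.94) and the glucocorticoid-induced gene TSC22D3 (-1.38), with a camera adjusted p of 0.0124 (adjusted p = 0.306 with an estimated correlation). The 9 epidermal growth factor ligands and receptors did not pass camera as a family (adjusted p = 0.155). Of these 6 fell and 2 rose, with EGFR lower (-1.34) and HBEGF higher (3.60). Of 141 ZNF zinc finger genes, 74 fell and 21 rose (median -0.26, camera adjusted p = 0.0116, adjusted p = 0.306 with an estimated correlation), of 8 semaphorins 7 fell and 0 rose (camera adjusted p = 0.0405, adjusted p = 0.306 with an estimated correlation), of 21 keratins 11 fell and 2 rose (camera adjusted p = 0.0405, adjusted p = 0.412 with an estimated correlation), and of 17 histone genes 10 rose and 3 fell (camera adjusted p = 0.0369, adjusted p = 0.333 with an estimated correlation).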
